A study of Mus musculus with 12 samples.

How the data were processed

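Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the glucocorticoid receptor (GR) was performed in BWTG3 cells, a mouse hepatoma line. Per the labels' protocols, cells were kept without serum for 24 h and then received 1 µM dexamethasone (Dex, a synthetic glucocorticoid), 1000 U/ml of the cytokine tumour necrosis factor (TNF), or TNF followed 1 h later by Dex. The sample titles put 3 libraries in the group NI, 3 in DEX, 2 in TNF and 3 in TNFDEX, and 1 further sample is the input. NI was treated as the group without either agent because its title names neither. The series' design text calls the replicates biological. No file of the input sample was used here, so input levels were known only through the ratios in the peak lists.

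Per the submitters' processing notes, CASAVA 1.8, Bowtie 1.0.0 and HOMER 4.6 were used with the mouse build mm10. Trimming, read filtering and duplicate handling are not given in the sources used here. Per the file headers, HOMER findPeaks was run in factor mode on each library separately against 1 input library. A peak needed a false discovery rate of 0.001, at least 4-fold more tags than the input and than the surrounding 10000 bp, and a Poisson p of 0.0001 for each. The deposited signal of each peak is its normalized tag count, the authors' number of tags in the peak scaled to 20000000 tags per library. Per the file headers, the lists also hold ratios, namely the fold of each peak over the input and over its surroundings. The deposited p-values are the Poisson p-values of findPeaks, the deposited fraction is its focus ratio, and the deposited score is its position-adjusted tag number. Scores, p-values and folds are the authors' values for single peaks and served only to describe or filter peaks within a list. A list holds no value where no peak was called, so a region without a call has an unknown level, not a level of 0. It may have failed on tags or on the ratio to the input or to its surroundings.

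Depth ranged from 39228805 to 51141996 tags per library per the file headers, and 0.106% to 2.91% of a library's tags fell in its nuclear peaks. Peak widths, set by the authors per library, lay between 139 and 177 bp. The weakest called peaks held few tags, with the lowest normalized tag count of a library at or below 6.6, so weak peaks carry a large counting error and absence of a call is poor evidence of absence of binding. Multiplying the normalized tag counts back by library size gave values within 0.15 of a whole tag for all peaks. Each such number was counted in a window centred on that library's own peak, so these values were not treated as read counts of a common feature. No count model was run, and the planned count models were replaced by limma on log2(normalized tag count), with no pseudocount because every tested value was above 0.

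The 11 lists were merged into 47493 regions wherever peaks shared at least 1 bp, with a median width of 173 bp. A region was called in a group when at least 2 of its libraries held a peak there. Regions called in every library of a group and in no library of another were said to separate the groups. The similarity of 2 lists was the Jaccard index of their regions, tested by exact one-sided permutation of the labels. Peak numbers, genomic positions and gene list counts were tested by exact two-sided permutation stratified by the other treatment, with 200 arrangements. Signal was tested with limma 3.58.1 in R 4.3.3 on regions called in every library of the groups compared, with scaling factors by the trimmed mean of M values (TMM) over those regions, and with Benjamini-Hochberg adjustment at 0.05. The largest peak was taken where a library had several in a region. Regions that gained or lost a call altogether were outside the signal test. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

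Gene positions came from a gene table of the assembly GRCm38.p6, which has the coordinates of mm10, with 21887 protein-coding genes. The table gave no strand, exons or start sites, so the planned distance to a transcription start was replaced by the distance to either end of the gene span, and exons and introns were not separated. A peak was near a gene end within 1 kb and distal beyond 50 kb of any protein-coding gene. A named region carries the nearest protein-coding gene, which need not be the gene it regulates. The planned motif shares were left out because no genome sequence was used here. The planned mean-depth filter of 20 tags and the other alternatives are in the closing section.

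The 11 gene lists were fixed before the data were examined, and all 215 genes in them were found in the table. They were glucocorticoid response, liver metabolism, NF-kB and TNF targets, acute phase, hepatocyte identity, circadian clock, AP-1 and immediate early genes, and GR with its cofactors, plus markers of macrophages, stromal or endothelial cells and neurons. A list gene counted as having a peak when a peak lay within 50 kb of either end of its span. The rule for named regions was also fixed beforehand. It took the 10 strongest regions separating DEX from NI, the 5 strongest separating regions per direction in the other comparisons, and the regions with the smallest p in the signal tests, 5 per direction and only past the threshold outside TNFDEX against DEX. In each list it took up to 4 members with the highest DEX normalized tag count at their strongest called region. Regions named outside this rule are said to have been chosen after their values were seen.

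The limma procedure was tested on simulated regions with known changes. The simulated libraries had independent noise (SD 0.25 on the natural log scale), no technical split between them and no loss of calls. The shares below may therefore not hold for the real libraries. In the TNFDEX against DEX design it recovered 46.0% of 2-fold and 100% of 4-fold changes, with 4.58% of its calls false. For DEX against NI the recovered shares were 45.5% and 100%, for TNFDEX against TNF 54.0% and 98.4%, and for TNF against NI 26.3% and 100%. The stratified permutation gave p under 0.05 in 4.8% of 500 simulations without an effect, and in 63.8% with a 2-fold effect, coded as 1 on the log2 scale. Merging and gene windows matched brute-force results in all 50 and 300 simulated cases.

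Same-numbered libraries were checked for pairing through the correlation of their deviations from the group means across tested regions. For DEX against NI the correlations were 0.517, 0.540 and 0.678, so the replicate number was taken as a block there and the blocked counts are printed beside that result. The other comparisons did not meet the rule of at least 3 pairs, each above 0.1.

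The libraries also split by their mitochondrial peaks. In 5 libraries (NI 3, DEX 3, TNFDEX 2, TNFDEX 3 and TNF 2) there were 2 very strong peaks in the mitochondrial genome, and in the other 6 there was 1 weaker peak. This split crosses the treatment groups and is called the mitochondrial batch below. The name stands for the split alone, since its origin was not tested. Results were recomputed with it as a stratum or a model term, a choice made after seeing the data. Each same-numbered pair of DEX and NI libraries lay within 1 mitochondrial batch. Differently numbered pairs of DEX and NI within a batch also correlated, at 0.374 and 0.486, while pairs across batches gave -0.535 to -0.625. The pairing by replicate number was therefore largely not separable from the batch. The 1 mitochondrial region called in all 11 libraries entered the signal tests, which were therefore also run on nuclear regions only.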

Results

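GR binding was mapped in BWTG3 mouse hepatoma cells in 11 libraries, 3 without either agent (NI), 3 with Dex (DEX), 2 with TNF (TNF) and 3 with TNF given 1 h before Dex (TNFDEX). Dex activates GR, a nuclear receptor that binds DNA at glucocorticoid response elements, and TNF is an inflammatory cytokine. The series asks how TNF alters GR binding to DNA in the setting of glucocorticoid resistance. Each library had its own peak list, with a depth of 39228805 to 51141996 tags, and every coordinate is given in mm10. Values at regions are normalized tag counts, the authors' tags per 20000000, as mean ± SD.

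Dex multiplied the GR peaks. The NI libraries held 4823 ± 2060 peaks (SD, n = 3), DEX 12152 ± 1448 (n = 3), TNF 6538 ± 3402 (n = 2) and TNFDEX 15091 ± 7033 (n = 3). Across both backgrounds Dex raised the number 2.50-fold (log2 1.32, exact two-sided stratified permutation p = 0.015, smallest possible 0.005), and 2.87-fold within mitochondrial batches (exact permutation p = 0.0139, the smallest possible). With TNF the number was 1.25-fold that without (exact permutation p = 0.425), and 1.42-fold within mitochondrial batches (exact permutation p = 0.0926, smallest possible 0.0185). Tags in nuclear peaks made up 0.278% ± 0.167 of all tags in NI, 1.52% ± 0.396 in DEX, 0.451% ± 0.384 in TNF and 1.90% ± 1.03 in TNFDEX. Leaving out TNF replicate 2 ended the Dex call (log2 1.04, exact permutation p = 0.05).

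**Figure D1:**
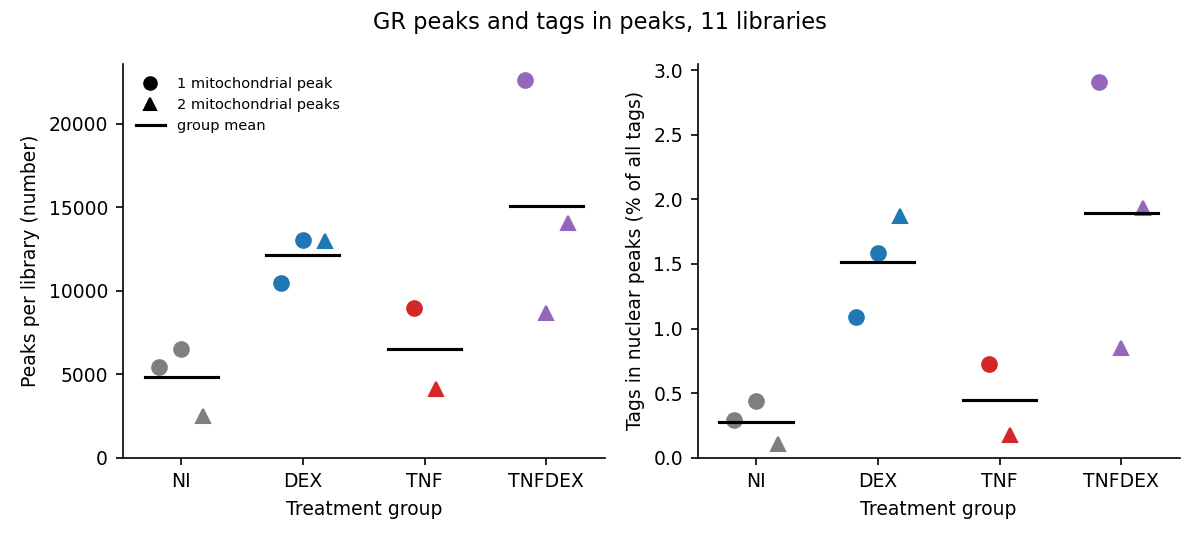
Number of GR peaks per library (left) and share of each library's tags in nuclear peaks in percent (right), by treatment group. Each point is 1 library, its shape shows whether 1 or 2 mitochondrial peaks were called, and the bar is the group mean. The DEX libraries held 10480 to 13021 peaks, above the 2524 to 6502 of the NI libraries.

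The comparison of DEX with NI asks where Dex brings GR to DNA. The strongest site that appeared with Dex lay 3.8 kb from Gm33049 (chromosome 15, 88850581 to 88850760) and reached 789 ± 136 in DEX. A region inside Zbtb16, a transcriptional repressor gene induced by glucocorticoids (chromosome 9, 48723703 to 48723882), reached 771 ± 354. A region 32.0 kb from Fkbp5, which encodes a cochaperone of GR and whose nearest gene is Armc12 (chromosome 17, 28518092 to 28518274), reached 694 ± 60.4. A region inside Bcl2l1, which encodes the survival factor Bcl-xL (chromosome 2, 152806153 to 152806358), reached 753 ± 97.3. A region inside Hmcn2 and 9.8 kb from Ass1, which encodes a urea cycle enzyme (chromosome 2, 31460391 to 31460570), reached 566 ± 317. None of these regions was called in any NI library.

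In all, 3815 regions were called in 3 of 3 DEX and 0 of 3 NI libraries, against 7 in the opposite pattern. Over the 10 ways to split these 6 libraries into 3 and 3, the real total of 3822 exceeded the highest other of 261, and 10 splits cannot give a share below 0.1. The other regions among the 10 strongest were 39.9 kb from Grhl2 (chromosome 15, 37192878 to 37193056, 587 ± 66.8), 17.9 kb from Armc12 (chromosome 17, 28512846 to 28513083, 503 ± 267), and inside Foxp1 (chromosome 6, 99175535 to 99175716, 557 ± 97.3), Cblb (chromosome 16, 52094751 to 52094929, 528 ± 219) and Nek7 (chromosome 1, 138571541 to 138571721, 501 ± 201). The strongest called in NI and never in DEX were weak and lay within Cpne1 (chromosome 2, 156111731 to 156111923, 14.9 ± 5.90), Rpl27 (chromosome 11, 101442419 to 101442642, 11.4 ± 1.89), Utp18 (10.2 ± 0.854), Nexn (9.90 ± 1.51) and H2aw (9.40 ± 1.91). Counting regions with at least 2 libraries, NI had 2008 and DEX 9286, and 74.8% of the NI regions were called in DEX as well. Requiring every library left 224 NI and 5658 DEX regions, and the NI count was 300 without NI replicate 1 and 291 without NI replicate 2. The 7 became 38, 47 and 167 without NI replicates 1, 2 and 3 and 14 without DEX replicate 2.

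Only 179 regions were called in all 6 NI and DEX libraries, and at these limma found 22 higher and 8 lower with Dex. The median of these regions was 0.76 higher with Dex on the log2 scale before TMM, so changes are relative to that shift. The largest rise was inside Tox, a gene for an HMG-box transcription factor (chromosome 4, 6914231 to 6914424), from 13.0 ± 6.41 to 379 ± 141 (log2 4.06, SE 0.40, limma adjusted p = 0.00185). Regions 4.3 kb from Arf6, which encodes a small GTPase (chromosome 12, 69367725 to 69367957), and inside Trim16 (chromosome 11, 62826371 to 62826593), Ccdc85a (chromosome 11, 28422981 to 28423214) and Atp10a (chromosome 7, 58746774 to 58747012) rose by 2.55, 2.03, 2.41 and 1.57. Regions inside Il1rap, which encodes a subunit of the interleukin-1 receptor (chromosome 16, 26590150 to 26590352), and nearest to Tgfbr3, Tex2, Bzw2 and Eef1a1 fell relative to the median (log2 -1.42, -0.92, -1.30, -0.99 and -1.11, limma adjusted p = 0.0201 to 0.0475). With library totals in place of TMM, 32 regions were higher and 0 lower, and these 5 lay between -0.07 and -0.56. With the replicate number as a block the counts were 33 higher and 16 lower, and with the mitochondrial batch as a term 37 and 23 (22 among nuclear regions only). All 22 higher and 8 lower calls had the same direction in both mitochondrial batches. Their selection from these same libraries favours that, so it is no separate support. Without NI replicates 1, 2 and 3 in turn the higher and lower counts were 8 and 0, 9 and 1, and 20 and 5, and without DEX replicates 1, 2 and 3 they were 16 and 1, 12 and 1, and 15 and 0.

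Genes of the glucocorticoid response list had GR peaks in most Dex libraries. Within 50 kb of their ends, 24.7 ± 0.577 of 28 had a peak per DEX library (n = 3) and 26.7 ± 1.15 per TNFDEX library (n = 3), against 11 ± 5 in NI and 14.5 ± 9.19 in TNF (n = 2). The effect of Dex was 12.9 genes (exact stratified permutation, two-sided, adjusted p = 0.0275 over 11 lists). The strongest members were Fkbp5, Zbtb16 with a further region inside it (449 ± 173), Zfp36, which encodes an mRNA-destabilising protein (392 ± 123), and the clock gene Per1 (344 ± 50.6), and none had a call at that region in an NI or TNF library. Counting regions called in at least 2 libraries, 17 of the 28 genes gained a region from NI to DEX, 7 had at least 1 in both, of which all but Zfp36 had more in DEX, and 4 had none in either (Cdkn1c, Anxa1, Lcn2 and Pik3r1).

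Genes of 6 further lists gained peaks with Dex, as protein-coding genes at large did, of which 14.2% had a region within 50 kb in NI and 35.3% in DEX. The effect of Dex was 8.83 of 24 hepatocyte identity genes, 8.67 of 23 liver metabolism genes, 6.50 of 24 acute phase genes, 4.67 of 17 circadian clock genes, 3.08 of 11 stromal and endothelial markers (each exact stratified permutation adjusted p = 0.0275) and 2.67 of 14 neuronal markers (exact permutation adjusted p = 0.0471). Against all protein-coding genes, acute phase genes (odds ratio 1.31), stromal and endothelial markers (1.53) and neuronal markers (1.02) were not over-represented in DEX (Fisher's exact adjusted p = 0.652, 0.652 and 1). Hepatocyte members included Hnf4a, which encodes a hepatocyte transcription factor, with 302 ± 150, Prox1 with 121 ± 34.8, and Krt8 and Krt18, which share a region of 97.5 ± 12.6. Metabolic members were Ass1, Igfbp1 (109 ± 15.3), the tyrosine aminotransferase gene Tat (77.2 ± 33.7) and Foxo3 (65.6 ± 14.8). Acute phase members were Lbp, the gene of lipopolysaccharide-binding protein (225 ± 100.9), Cp (51.7 ± 8.40), Agt (43.5 ± 9.05) and Fga (14.9 ± 3.17), and clock members besides Per1 were Per2 (142 ± 9.06), Cry2 (129 ± 15.3) and Ciart (83.2 ± 18.9). The members named are the strongest, whether or not the gene gained a peak, and Ciart had another peak within 50 kb in 3 of 3 NI libraries. Stab2 (74.9 ± 28.9, 24.4 in 2 NI libraries), Dcn (44.1 ± 8.39, 31.9 in 2 NI libraries) and Gria2 (41.6 ± 12.4, 31.0 in 3 NI libraries) had a peak within 50 kb in 3 of 3 NI libraries as well, and the strongest other members were Col1a1 (38.7 ± 10.9) and Kdr (36.3 ± 5.35) among stromal and Snap25 (34.4 ± 11.7) among neuronal markers.

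The remaining 4 lists did not pass in the test stratified by the other treatment alone. NF-kB and TNF targets differed by 6.67 of 30 genes with Dex (exact permutation adjusted p = 0.171). Their strongest members in DEX, whether or not gained, were Nfkbia, the gene of the NF-kB inhibitor IkBa (179 ± 22.7), Nfkbie (41.0 ± 7.46), Bcl3 (40.7 ± 8.15) and Tnf (24.3 ± 5.2). The Bcl3 region had 39.05 in 2 NI libraries and 76.5 in 1 TNF library. The Tnf region had 13.0 in 1 NI library and 20.3 in 1 TNF library. AP-1 and immediate early genes differed by 5.67 of 20 (exact permutation adjusted p = 0.124). Strongest in DEX among them were Myc (224 ± 64.4), Maff (100 ± 46.1), Dusp6 (49.2 ± 10.8, 23.8 in 1 TNF library) and Dusp1 (37.9 ± 17.9, 16.8 in 1 NI library). For NF-kB targets and for AP-1 genes these p-values do not take the mitochondrial batch into account. Within each batch and TNF background, every library with Dex held more genes of either list than every library without. GR and its cofactors differed by 1.17 of 15 (exact permutation adjusted p = 0.605), with regions at the GR gene Nr3c1 itself (54.5 ± 13.3) and Ncoa3 (21.2 ± 11.5). Macrophage markers differed by 1.75 of 12 (exact permutation adjusted p = 0.248). Strongest in DEX among these were Cd14 (79.8 ± 54.7), Adgre1 (36.4 ± 24.4), Ptprc (29.3 ± 14.3) and Itgam (22.9 ± 5.37). Without DEX replicate 3 the means of Cd14 and Adgre1 were 48.6 and 22.4. When the 2524 strongest peaks of each library were used, only glucocorticoid response (12.0 genes) and hepatocyte identity (4.58 genes) passed. The Dex effects on acute phase genes (-0.833) and neuronal markers (-0.667) then turned negative. Those on NF-kB and TNF targets, AP-1 genes and cofactors turned negative as well. No list passed without DEX replicate 2, DEX replicate 3, TNFDEX replicate 1 or TNFDEX replicate 3 (0 lists each), and 3 did without TNF replicate 2. No list passed for TNF, where the lowest adjusted p was at acute phase genes (5.17 of 24 genes, exact permutation p = 0.05, adjusted p = 0.55).

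**Figure D2:**
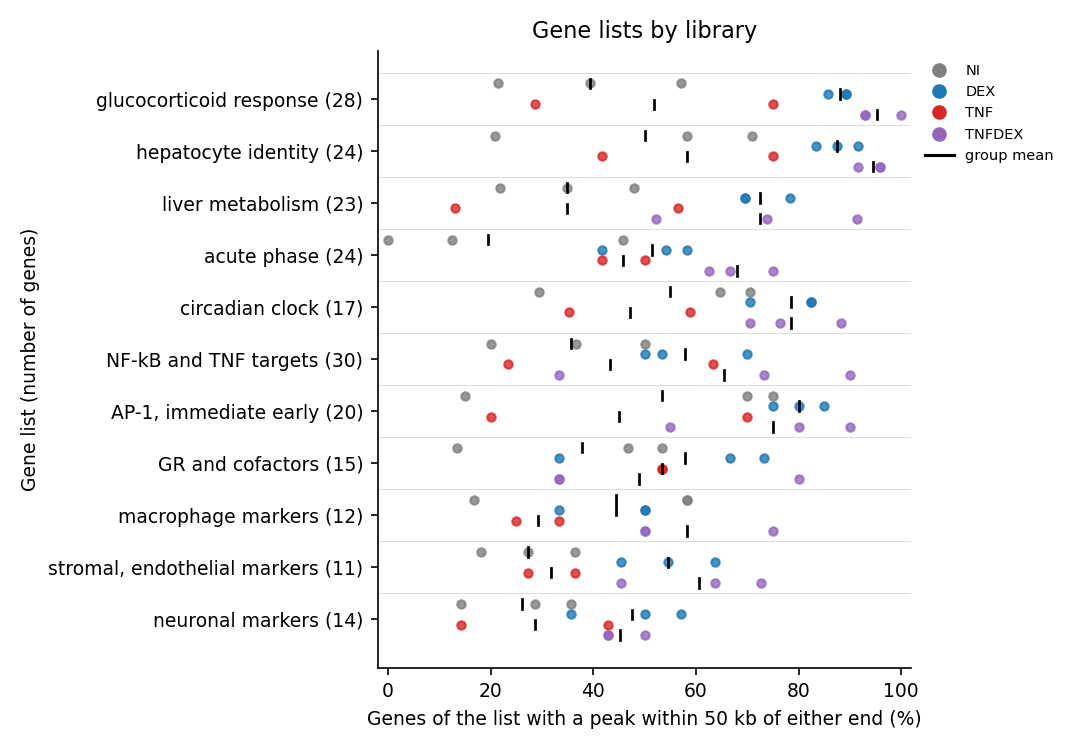
Share of each list's genes, in percent, with a GR peak within 50 kb of either end of the gene, for the 11 lists. Each point is 1 library, colours are treatment groups, and the bar is the group mean. Glucocorticoid response genes had a peak in 24 to 25 of 28 cases in the DEX libraries and in 6 to 16 in the NI libraries.

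Against all 21887 protein-coding genes, of which 35.3% had a DEX region within 50 kb, list genes were over-represented for glucocorticoid response (24 of 28, odds ratio 11.1, Fisher's exact adjusted p = 5.78e-07), hepatocyte identity (21 of 24, odds ratio 12.9, 9.97e-07), liver metabolism (16 of 23, odds ratio 4.20, 0.004), circadian clock (12 of 17, odds ratio 4.41, 0.00845) and AP-1 genes (15 of 20, odds ratio 5.52, 0.00185). In TNFDEX these 5 lists passed, and NF-kB and TNF targets (19 of 30, odds ratio 2.80, Fisher's exact adjusted p = 0.0161) and acute phase genes (15 of 24, odds ratio 2.70, 0.0303) did as well. Neighbouring genes can share a region, as Saa1 to Saa4 did. With 1 gene per cluster, a choice made after seeing the data, acute phase genes no longer passed (10 of 16, odds ratio 2.70, Fisher's exact adjusted p = 0.107). NF-kB and TNF targets did (17 of 27, odds ratio 2.76, Fisher's exact adjusted p = 0.0178), as did the other 5 lists in DEX and in TNFDEX. In NI only AP-1 genes passed (10 of 20, odds ratio 6.04, Fisher's exact adjusted p = 0.00173), and in TNF no list did. Whether a list's odds differed between DEX and TNFDEX was not tested by this comparison.

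The share of GR peaks near gene ends was lower with Dex. Their number was 1.20-fold (exact two-sided permutation p = 0.62, and 1.36-fold within mitochondrial batches, exact permutation p = 0.0972) and that of other peaks rose 2.77-fold (exact permutation p = 0.01). Of each library's peaks, 19.6% ± 3.12 lay within 1 kb of a gene end in NI, 10.3% ± 4.20 in DEX, 15.8% ± 2.49 in TNF and 7.36% ± 1.40 in TNFDEX. The effect of Dex on this share was -8.89 percentage points (exact two-sided stratified permutation p = 0.005, the smallest possible), and -8.84 points within mitochondrial batches (exact permutation p = 0.0139). The share inside gene spans changed by -4.51 points with Dex (exact permutation p = 0.005) and by -2.46 with TNF (exact permutation p = 0.02), and the latter was -2.19 within mitochondrial batches (exact permutation p = 0.0556). The share beyond 50 kb of any gene changed by 2.15 points with Dex (exact permutation p = 0.03). TNF gave -3.32 points near gene ends (exact permutation p = 0.11) and 1.73 points beyond 50 kb (exact permutation p = 0.09). Leaving out any of 7 libraries ended the distal call with Dex, and leaving out any of 8 ended the call inside gene spans with TNF.

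**Figure D3:**
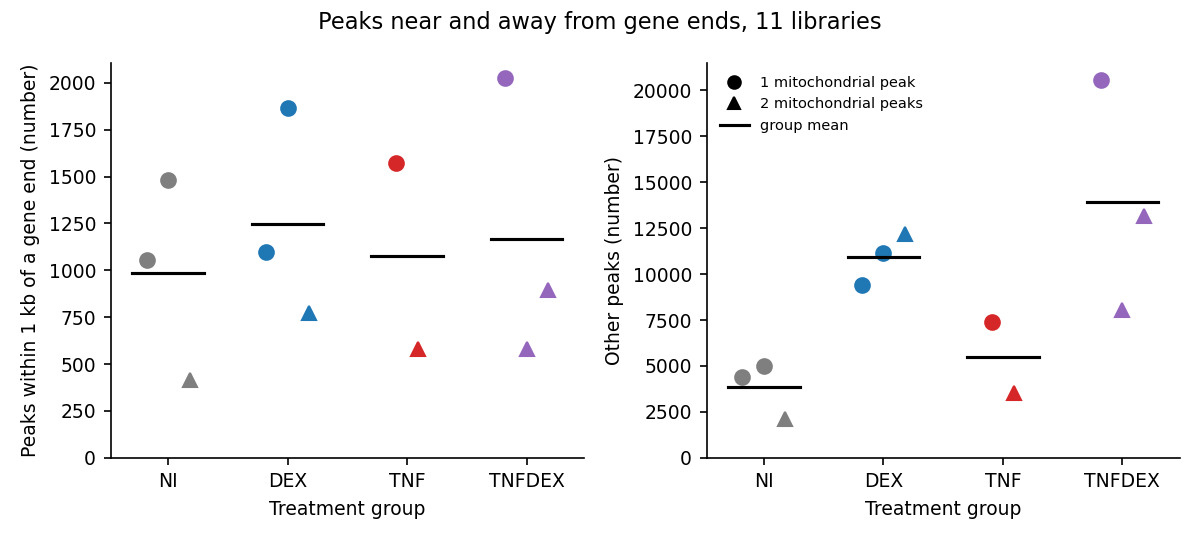
Number of peaks within 1 kb of a gene end (left) and number of all other peaks (right) per library, by treatment group. Each point is 1 library, its shape shows whether 1 or 2 mitochondrial peaks were called, and the bar is the group mean. Peaks near gene ends ranged from 1057 to 2025 in libraries with 1 mitochondrial peak and from 417 to 894 in those with 2.

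The comparison of TNF with NI asks whether TNF alone moves GR on DNA. Regions separating the groups were few and weak, and the strongest of those called in 2 of 2 TNF and 0 of 3 NI libraries were inside Slc35b2 (chromosome 17, 45563845 to 45564017, 25.8 ± 13.7, n = 2), 1.7 kb from Fam20c (24.8 ± 13.6), 0.3 kb from Junb, which encodes an AP-1 subunit (chromosome 8, 84976470 to 84976727, 23.3 ± 3.68), 133.9 kb from Slc4a3 (22.7 ± 21.0) and 39.6 kb from Prickle1 (21.5 ± 1.84). The Junb region was also called in 3 of 3 TNFDEX libraries (27.9) and in 1 DEX library. There were 116 such regions and 9 in the opposite pattern, and the real total of 125 was below the 1489 of the highest other split and the 1060 of the split that follows the mitochondrial batch. The 116 became 305 without NI replicate 2, and 3163 or 5232 without TNF replicate 1 or 2, and the 9 became 48, 54 and 190 without NI replicates 1, 2 and 3 and 71 without TNF replicate 1. The 9 included Cpne1, Parpbp (11.5 ± 2.17), Rpl27, Nexn and Ptp4a1 (9.07 ± 1.88). At the 152 regions called in all 5 libraries limma found 0 changes, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.996. With the mitochondrial batch as a term 0 were higher and 1 was lower, with 16 at an unadjusted p under 0.05. It lay inside Cpsf1 (chromosome 15, 76607378 to 76607661, 14.8 ± 2.26 in NI and 10.5 ± 3.39 in TNF, log2 -1.16, limma adjusted p = 0.0319) and was chosen after its values were seen. Before TMM the median of the tested regions was 0.34 higher with TNF on the log2 scale, and 0.59 with that term. The -1.16 is relative to that shift. Only 924 regions were called in both TNF libraries, 63.5% of them also in NI and 82.1% in DEX. With 2 libraries the self-test, simulated without a mitochondrial batch, recovered 26.3% of 2-fold changes.

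The comparison of TNFDEX with DEX asks how TNF changes GR binding once Dex is present. Most of the Dex sites were bound in both. Of the 3815 regions that separated DEX from NI, 95.02% were called in at least 2 TNFDEX libraries, 74.8% in all 3 and 12 regions in none. The sites at Zbtb16, Gm33049, Bcl2l1 and the Fkbp5 locus had 835, 717, 711 and 550 in TNFDEX, against 771, 789, 753 and 694 in DEX. Counting at least 2 libraries, DEX had 9286 and TNFDEX 11395 regions, and the 7441 they shared were 80.1% of the DEX and 65.3% of the TNFDEX regions. Without TNFDEX replicate 1 the TNFDEX and shared counts were 6234 and 4920, and without TNFDEX replicate 3 they were 6109 and 4944.

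**Figure D4:**
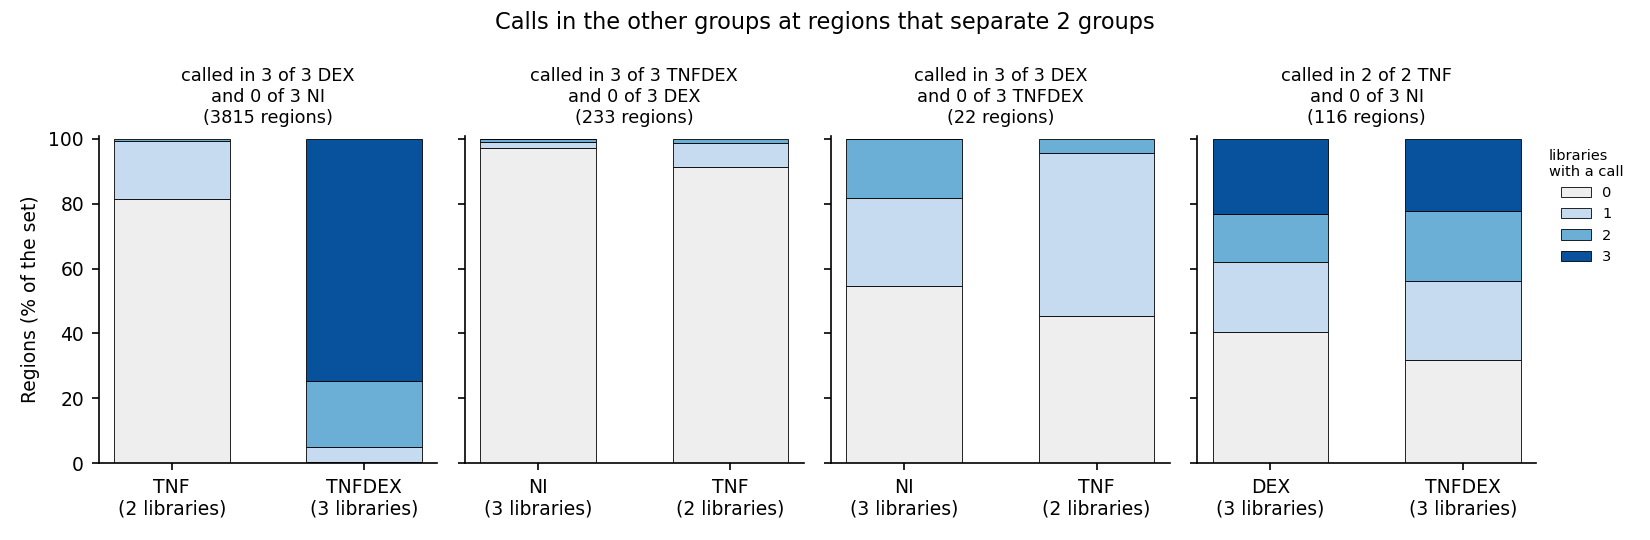
Calls in the other groups at 4 sets of regions that separate 2 groups, as percent of each set. Shading gives the number of libraries with a call there. Of the 3815 regions called in all DEX and no NI libraries, 74.8% were called in all 3 TNFDEX libraries and 81.3% in no TNF library.

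Few of the 4023 regions called in all 6 libraries passed the signal test between TNFDEX and DEX. In limma 1 region was higher with TNF and 0 were lower. At an unadjusted p under 0.05 there were 257, 197 higher and 60 lower, where chance gives 201, and 551 with the mitochondrial batch as a term. The region that rose was 89.7 kb from Cemip2, which encodes a cell-surface protein linked to hyaluronan turnover (chromosome 19, 21947945 to 21948163), at 12.7 ± 2.45 in DEX and 68.6 ± 29.6 in TNFDEX (log2 2.21, SE 0.27, limma adjusted p = 0.0494). Next by p, as values only, came regions inside Ifitm2, an interferon-induced gene (chromosome 7, 140956475 to 140956668, 41.0 ± 7.19 against 181 ± 33.4, log2 1.99, limma adjusted p = 0.0545), 4.9 kb from Rgs4 (chromosome 1, 169752464 to 169752662, log2 1.98), 61.9 kb from Acsl1, which encodes an enzyme that activates fatty acids (chromosome 8, 46409032 to 46409225, log2 1.92), and inside Cd33 (chromosome 7, 43530394 to 43530643, log2 1.42). Toward lower signal the smallest p were at regions whose nearest genes were Arnt2 (chromosome 7, 84419721 to 84419935, log2 -0.95), Sesn1 (chromosome 10, 41889659 to 41889843, -0.71), Klf14 (chromosome 6, 31148311 to 31148496, -0.87), Slc38a2 (chromosome 15, 96833243 to 96833454, -0.70) and Capn9 (chromosome 8, 124586168 to 124586366, -0.67), none with a limma adjusted p below 0.404. The Capn9 region lay inside that gene and 16.6 kb from Agt, and is the region given above for Agt. The mitochondrial batch as a term gave 28 higher and 1 lower, library totals in place of TMM gave 0 with or without that term, and leaving out any library except TNFDEX replicate 1 (5 higher) gave 0. The median of these regions was 0.14 higher with TNF on the log2 scale before TMM.

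**Figure D5:**
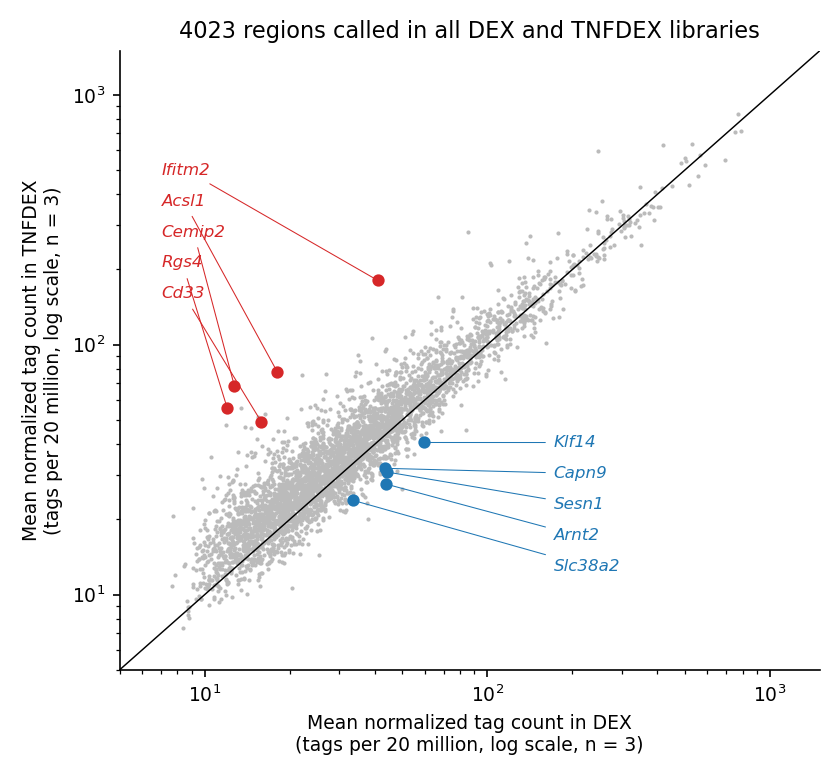
Mean normalized tag count in DEX and in TNFDEX (tags per 20000000, log axes, n = 3 each) at the 4023 regions called in all 6 libraries. Red and blue mark the 5 regions per direction with the smallest p, and the line marks equal signal. The Cemip2 region lay at 12.7 in DEX and 68.6 in TNFDEX.

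Without a batch term, no list's regions passed a test for a common direction between TNFDEX and DEX. For differences in either direction, the mixed test of fry passed for NF-kB and TNF targets (adjusted p = 0.000739), acute phase (0.00850), circadian clock (0.0145) and stromal regions (0.0148), and with the mitochondrial batch as a term for AP-1 (0.0240) and neuronal regions (0.0175) as well. Among 54 regions of glucocorticoid response genes the median log2 difference was -0.11, among 26 of hepatocyte identity genes -0.04, among 18 of liver metabolism genes -0.05 and among 10 of AP-1 genes -0.04. The 10 circadian clock regions had a median of -0.41 with the smallest camera p of the lists in that fit (0.0133, adjusted p = 0.146, adjusted p = 0.760 with an estimated correlation), and no list passed in camera with either correlation. With the mitochondrial batch as a term the smallest camera p was that of glucocorticoid response (0.00674, adjusted p = 0.0741, adjusted p = 0.760 with an estimated correlation), whose median was then -0.21. The medians were 0.11 for 6 NF-kB and TNF target regions, 0.07 for 5 acute phase regions, 0.07 for 6 stromal regions, 0.10 for 4 macrophage, -0.18 for 4 cofactor and -0.15 for 3 neuronal regions. Per1 (344 against 296 ± 101.7), Nfkbia (179 against 163 ± 93.5), Tat (77.2 against 100 ± 31.8) and Hnf4a (302 against 323 ± 122) differed between DEX and TNFDEX by less than the spread between replicates. Over all regions tested 0 of these list regions passed in limma, and with the mitochondrial batch as a term Csf1 and a Dcn region did (log2 1.62 and 1.75, limma adjusted p = 0.00996 and 0.00475). With that term NF-kB and TNF targets as a group passed in fry (adjusted p = 0.0370) but not in camera (adjusted p = 0.101, adjusted p = 0.760 with an estimated correlation). Without that term and adjusted over the list alone, 2 NF-kB target regions passed (Csf1 and Tnfaip3), 1 clock region in the window of Dbp and nearest to Sec1, 1 stromal region 37 kb from Dcn, and none in the other lists. With the term 1 acute phase region passed as well. These regions were chosen after their values were seen.

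The 5 strongest regions that gained calls with TNF on top of Dex reached 52.5 to 65.4. The median in TNFDEX at the 4023 regions called in all 6 libraries was 34.2. The strongest lost region reached 36.1 in DEX, where that median was 29.4. There were 233 regions called in 3 of 3 TNFDEX and 0 of 3 DEX libraries and 22 in the opposite pattern. The greater depth of every TNFDEX library can add to the gained calls. The real total of 255 was below the 892 of the highest other split and the 870 of the split that follows the mitochondrial batch. The strongest gained regions were nearest to Gm50595 (chromosome 2, 75285359 to 75285547, 65.4 ± 21.3), Coa7 (57.6 ± 15.1), Ptprr (57.1 ± 16.2), Parva (53.5 ± 14.2) and Dusp10, a phosphatase gene for stress-activated kinases (chromosome 1, 184260865 to 184261041, 185.3 kb away, 52.5 ± 13.8). Among the strongest lost regions were those nearest to Usp18, an interferon-induced gene (chromosome 6, 121240799 to 121240976, 36.1 ± 5.69), Kcnh1 (32.2 ± 2.55), Dlx3 (24.2 ± 6.52) and Fmn1 (16.1 ± 1.66). The gained count was 380, 1255 and 362 without TNFDEX replicates 1, 2 and 3 and 852 without DEX replicate 3. The lost count was 310 and 53 without TNFDEX replicates 1 and 3, and 105, 71 and 267 without DEX replicates 1, 2 and 3.

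The comparison of TNFDEX with TNF gives the effect of Dex when TNF is present. The strongest sites absent with TNF alone were largely those absent in NI, inside Zbtb16 (835 ± 286), near Gm33049 (717 ± 244), inside Cblb (637 ± 211), 33.1 kb from Slc45a1 (chromosome 4, 150685208 to 150685394, 629 ± 210) and 55.6 kb from Eif3h (chromosome 15, 51730843 to 51731025, 595 ± 174, with 246 in DEX). In total 3961 regions were called in 3 of 3 TNFDEX and 0 of 2 TNF libraries and 77 in the opposite pattern, led by Macrod2 (36.8 ± 32.5), Fam20c, B4galt5 (20.6 ± 1.77), Zswim2 (18.8 ± 12.9) and Pced1b (15.9 ± 4.88). The total of 4038 compares with up to 3254 in the other splits of these 5 libraries. Without TNFDEX replicate 2 the 3961 became 7210, and the 77 became 199 without TNFDEX replicate 1 and 3106 or 2883 without TNF replicate 1 or 2. At the 508 regions called in all 5, limma found 58 higher and 5 lower, relative to a median that was 0.56 higher with Dex on the log2 scale before TMM. Regions inside Nhej1, a gene of DNA double-strand break repair (chromosome 1, 74971670 to 74971931), rose from 15.2 ± 5.87 to 357 ± 148 (log2 3.85, SE 0.35, limma adjusted p = 4.5e-05), and 42.8 kb from Akr1d1, which encodes a steroid 5-beta-reductase (chromosome 6, 37617507 to 37617984), from 12.7 ± 4.31 to 223 ± 79.8 (log2 3.45, limma adjusted p = 8.4e-05).

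Regions 447.4 kb from Pdcd1 (log2 2.72), inside Glra3 (2.33) and 33.9 kb from Tmem14a (2.39) rose as well, and regions nearest to Gm50595 (-1.29), Lef1 (-1.23), Plk2 (-1.37), Mtg2 (-1.14) and Siah1a (-1.28) fell relative to the median (limma adjusted p = 0.0131 to 0.0491). With library totals in place of TMM 7 were higher and 0 lower, and with the mitochondrial batch as a term 99 and 73 (72 among nuclear regions only). Without TNFDEX replicates 1, 2 and 3 in turn the counts were 61 and 12, 31 and 0, and 33 and 1. Without TNF replicate 1 or 2, which leaves a lone TNF library assumed to vary like the others, they were 63 and 17, and 76 and 51. All 58 higher and 5 lower calls had the same direction in both mitochondrial batches, which their selection from these same libraries favours. Of 3 hepatocyte identity regions tested here, the only list with enough, the median was -0.02 (camera adjusted p = 0.857, adjusted p = 0.867 with an estimated correlation).

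The Dex effects with and without TNF share no libraries. At the 118 regions called in all 11 libraries they correlated across regions (r = 0.889, regions are not independent replicates), and the 8 regions higher with Dex in TNFDEX against TNF were all among the 17 higher in DEX against NI, where independent lists would share 1.15. The test of the difference between the Dex effects found 0 of 118 regions in limma, 0 at an unadjusted p under 0.05, with a smallest adjusted p of 0.982. The lists of peaks were more alike within than between groups for DEX and NI (difference of mean Jaccard indices 0.142) and for TNFDEX and TNF (0.166), each at the smallest possible exact one-sided permutation p of 0.1. The excess came from the pairs with Dex (mean 0.394 in DEX and 0.343 in TNFDEX), since the NI pairs (0.0858) were less alike than NI with DEX (0.0979). The TNF pair (0.0761) was less alike than TNF with TNFDEX (0.111). For TNFDEX and DEX the difference was 0.000794 (exact permutation p = 0.4) and for TNF and NI -0.0266 (exact permutation p = 0.7). The pairs DEX against NI, TNFDEX against DEX, TNF against NI and TNFDEX against TNF differed 2.71-, 1.16-, 1.36- and 2.30-fold in peak number, with exact permutation p of 0.1, 0.7, 0.6 and 0.3 and a smallest possible p of 0.1 in each.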

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

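The tests of peak number, of immunoprecipitation, of gene ends, of the splits and of nuclear regions alone below were chosen only after the results were seen, as were Ppara, Csf1 and Irak3. The peak lists hold calls in the mitochondrial control region, between 15396 and 16135. The region from 15396 to 15624 was called in all 11 libraries and was therefore 1 of the regions in each signal test. In 5 libraries (NI 3, DEX 3, TNFDEX 2, TNFDEX 3 and TNF 2) these peaks summed to a normalized tag count of 70983 to 108166 and lay 71.6- to 144-fold above input, and in the other 6 they summed to 1290 to 6953. The sum passed no test for Dex (log2 0.16, exact two-sided permutation p = 0.91) or TNF (log2 2.12, exact permutation p = 0.235). With the mitochondrial batch as a term, this region itself passed as lower in DEX than in NI (log2 -0.80, limma adjusted p = 0.0433) and in TNFDEX than in TNF (log2 -1.28, limma adjusted p = 6.10e-05). Both falls are relative to TMM over shared regions, whose median was higher with Dex before TMM. The normalized tag counts at this region were 1290, 2275 and 46788 in NI and 1542, 2268 and 43938 in DEX. They were 6953 and 46387 in TNF and 3812, 36247 and 54519 in TNFDEX. The batch is defined by the number of mitochondrial peaks, so this region is no independent test with that term. With nuclear regions only, the lower counts with that term were 22 and 72 in place of 23 and 73. No biological explanation of these peaks was tested.

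Few regions differed in signal between TNFDEX and DEX. Of the 10 splits of these 6 libraries, 2 gave at least as many regions as the real 1, and the highest other, 997, was the split that follows the mitochondrial batch, which points to a structure of the libraries. With the batch as a term 29 regions differed, among them Ppara, Csf1 and Irak3, so this structure may hide differences. With that term 1 of the 9 splits that could be fitted, the real one, gave as many (29, highest other 0), and these splits are too few for a share under 0.05. The 29 became 0 with library totals in place of TMM, and the TNF differences of the batches correlated at r = 0.123 across 4023 regions, so whether TNF leaves the signal at most shared regions as Dex alone sets it cannot be told apart from noise in few libraries.

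More peaks were called with Dex, at sites such as Zbtb16 and Fkbp5. Library size differed by 0.14 on the log2 scale (1.10-fold, exact permutation p = 0.06), far below the peak numbers, and within mitochondrial batches the Dex effect was 1.52 (2.87-fold, exact permutation p = 0.0139). Binding of GR to further sites and stronger enrichment of the same sites cannot be told apart. At equal list length the lists were more alike within than between groups by a Jaccard difference of 0.266, but the indices of NI pairs (0.0473 to 0.353) overlapped those of NI with DEX (0.0184 to 0.195). The 179 shared regions were 0.76 higher with Dex in the median before TMM. A single factor of immunoprecipitation for all sites, of the size seen at shared regions, is argued against. Divided by the 95th percentile of the factors of shared regions (4.86-fold), 848 regions called in every DEX library stayed at 2 times the calling limit or more, and 27.9% of these were called in an NI library. For TNFDEX and TNF the share was 31.6% of 842 regions. Of regions of that level in 2 DEX or 2 TNFDEX libraries, 86.2% and 80.4% were called in the remaining one. The shared regions had to be called in every library, also without Dex, which leaves out sites with a larger rise. A larger factor common to such sites, or one that differs between sites, was not tested and stays open. For the signal of DEX against NI, 1 of 10 splits, the real one, gave as many regions (30, highest other 0), also against the 3 other splits that part every same-numbered pair, and these are too few for a share under 0.05.

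The share of peaks near gene ends was lower with Dex. Longer lists that add weak peaks away from genes are argued against, since the Dex effect was -14.1 percentage points at equal number. Another explanation is a set of open gene ends called whatever the treatment. By number alone it could hold, since peaks near gene ends were 1.20-fold with Dex (exact permutation p = 0.62) while other peaks rose 2.77-fold (exact permutation p = 0.01). Whether the same gene ends were called was not compared. Only 118 regions of any kind were called in all 11 libraries, against 417 to 2025 peaks near gene ends per library. This argues against 1 such set called in full in every library. Within mitochondrial batches the number near gene ends was 1.36-fold, higher with Dex in each of 4 strata (exact permutation p = 0.0972). These values run against a net fall in their number, but with this p it stays open, as does loss at single gene ends, which was not tested.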

How the results depend on the processing

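The mitochondrial batch, the intensity trend, the batch with library totals and nuclear regions only, with or without the batch, were chosen as tests only after the data were seen, and the other alternatives were planned. Of the results that answer a comparison, 153 values stayed within the set bounds under the alternatives other than leaving out a library, 58 moved and 1 reversed. Leaving out a library gave 297 that stayed, 57 that moved, 5 that reversed, 1 that lost and 1 that gained its call. Of values for single lists, positions and regions, 259 stayed, 39 lost and 13 gained their call and 9 reversed, and with a library left out 573 stayed, 91 lost and 5 gained their call and 15 reversed. Where fewer libraries or regions enter, the counts change by construction, and elsewhere the cause was not tested. Merging by centres within 100 bp, chromosomes 1 to 19 and X alone, the filter of 20 tags, the nearest gene alone and a 5 kb limit for gene ends moved none of the results that answer a comparison.

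With at least 8-fold over input, NI had 1170 and TNF 514 regions. Regions called in every NI and no DEX library were 2, DEX and no TNFDEX 14, TNF and no NI 64, NI and no TNF 5, and TNF and no TNFDEX 38. Requiring every library gave 224 NI, 5658 DEX, 5777 TNFDEX and 4023 shared DEX and TNFDEX regions. With an equal number of strongest peaks DEX had 2383, TNF 569, TNFDEX 2445 and DEX with TNFDEX 1791 regions. Separating regions were then 1177 (DEX, no NI), 59 (NI, no DEX), 58 (TNFDEX, no DEX), 37 (TNF, no NI), 14 (NI, no TNF), 1224 (TNFDEX, no TNF) and 239 (TNF, no TNFDEX), and 2 gene lists passed with Dex. Dex effects reversed there, in genes, for NF-kB targets (-2.58), acute phase (-0.833), AP-1 (-0.833), cofactors (-1.08) and neuronal markers (-0.667), and TNF effects for glucocorticoid response (-0.667) and stromal markers (-0.917). With a window of 10 kb 3 lists passed with Dex, and TNF effects reversed for cofactors (-1) and stromal markers (-0.167). The common floor turned the list similarity of TNFDEX and DEX to -0.000441.

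In limma, regions higher in TNFDEX than in DEX numbered 28 with the mitochondrial batch as a term (1 lower), 2 with an intensity trend, 15 with a replicate block, and 0 with library totals, with the batch and library totals, and with all 11 libraries. DEX against NI gave 37 higher and 23 lower with the batch, 48 and 0 with the batch and library totals, 13 and 0 with all 11 libraries, 33 and 16 with the block, 5 lower with the trend and 0 lower with library totals. TNF against NI gave 1 lower with the batch. TNFDEX against TNF gave 99 higher and 73 lower with the batch, 153 and 0 with the batch and library totals, 7 and 0 with library totals, 14 and 0 with the block, and 10 and 0 with all 11 libraries. With nuclear regions only the counts were 1 and 0 for TNFDEX against DEX, 23 and 9 for DEX against NI, 0 and 0 for TNF against NI and 59 and 5 for TNFDEX against TNF. With the batch as well they were 28 and 1, 37 and 22, 0 and 1, and 99 and 72. The block followed the replicate number, whose pairs correlated at 0.37, -0.367 and 0.575 for TNFDEX and DEX, 0.512 and -0.650 for TNF and NI, and 0.506 and 0.452 for TNFDEX and TNF, so outside DEX and NI it was used only here.

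Leaving out 1 library in turn, the Dex effect on log2 peak number ran from 1.04 (without TNF 2, exact permutation p = 0.05) to 1.60, TNFDEX against DEX from -0.13 (without TNFDEX 1) to 0.56 and TNF against NI from -0.11 (without TNF 1) to 1.00. Regions ran from 291 to 2008 in NI, 6109 to 11395 in TNFDEX and 4920 to 7441 in DEX with TNFDEX. Separating regions ran from 7 to 167 (NI, no DEX), 233 to 1255 (TNFDEX, no DEX), 22 to 310 (DEX, no TNFDEX), 116 to 5232 (TNF, no NI), 9 to 190 (NI, no TNF), 3961 to 7210 (TNFDEX, no TNF) and 77 to 3106 (TNF, no TNFDEX). List similarity ran from -0.0365 (without DEX 1) to 0.0242 for TNFDEX and DEX and from -0.0686 to 0.0204 (without TNF 1) for TNF and NI. The TNF effect near gene ends ran from -4.40 points (without DEX 3, exact permutation p = 0.03) to -2.30, and lists passing with Dex from 0 to 8. TNF effects in genes ran from -0.5 to 6 for glucocorticoid response, -0.667 to 5.33 for NF-kB targets, -0.167 to 3.83 for hepatocyte identity, -1.75 to 0.333 for circadian clock, -3.83 to 1.17 for AP-1, -0.667 to 1.08 for cofactors and -0.917 to 0.333 for macrophage markers. In limma the counts ran from 0 to 5 higher for TNFDEX against DEX, 8 to 20 higher and 0 to 5 lower for DEX against NI, and 31 to 76 higher and 0 to 51 lower for TNFDEX against TNF, where a lone TNF library was assumed to vary like the other libraries.

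The planned count models and their size factors were not run because each library's tags were counted in its own peak window, and the planned motif shares were not run because no genome sequence was used here. Depth limits the weak peaks, since the lowest normalized tag count of a library was at or below 6.6. With 3 libraries per group limma recovered 46.0% of 2-fold changes in regions simulated without a mitochondrial batch.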

Other observations

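The test of sites bound with TNF alone was chosen only after the result was seen, as were the regions named here and the comparison by mitochondrial peaks. Some inflammatory genes had calls with TNF and Dex together, in the group with the deepest libraries. A region 0.1 kb from Saa3, an acute phase gene (chromosome 7, 46719614 to 46719834), was called in 3 of 3 TNFDEX libraries (25.4 ± 7.58), 1 DEX library (21.5) and no NI or TNF library. Another, 1.4 kb from Saa3 (chromosome 7, 46710510 to 46710738), went the other way, called in 2 of 2 TNF (10.1), 1 NI, 1 DEX and 0 TNFDEX libraries. A region 0.6 kb from Lcn2 (chromosome 2, 32388193 to 32388404, 10.0 ± 0.929) was called in 3 of 3 TNFDEX libraries and nowhere else. Regions at Cxcl1, a chemokine gene (chromosome 5, 90891062 to 90891371, 24.5 ± 8.76), and Traf1 (chromosome 2, 34951709 to 34951925, 15.7 ± 4.21) were called in 3 of 3 TNFDEX and 1 DEX library each, Cxcl1 also in 1 TNF library.

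Of the 233 regions called in every TNFDEX and no DEX library, 2 lay near NF-kB and TNF targets against 35 of the other 11162 TNFDEX regions (odds ratio 2.75, 95% interval 0.319 to 10.8, Fisher's exact p = 0.175), which leaves open whether such genes are favoured. Of the 233, 8.58% (20 of 233) were called in a TNF library, against 24.7% of 5544 other regions called in every TNFDEX library at matched strength. This lower share runs against most of the 233 being sites bound with TNF alone. The question stays open, since the TNF lists are short. The 24.7% fell just under the share required for a verdict, a limit also chosen after the result was seen. Among all other TNFDEX regions, 31.4% (3506 of 11162) were called in a TNF library.

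With the mitochondrial batch as a term, 28 regions were higher in TNFDEX than in DEX, by 0.93 to 2.27 on the log2 scale. All 28 were higher in both batches, which their selection from these same libraries favours. The 28 regions were not tested in other libraries. The 28 regions included Ppara, which encodes a lipid-sensing nuclear receptor (85.8 ± 38.8 against 283 ± 70.3), Csf1, a macrophage growth factor gene (22.1 ± 2.99 against 75.9 ± 22.6), and Irak3, an inhibitor of interleukin-1 receptor signalling (26.6 ± 4.56 against 65.2 ± 21.0). Their median with Dex alone, 16.1, lay at percentile 16.2 of the 4023 tested regions, so they may be sites that Dex alone binds weakly. Of the 28, 23 were called in no TNF library, as were 81.3% of the 3815 regions that separated DEX from NI. Weak values regress upward when regions are picked for a rise, so this percentile is in part built in.

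Peaks near gene ends were 2.55-fold more numerous in libraries with 1 mitochondrial peak than in those with 2, compared within groups (1057 to 2025 against 417 to 894, exact two-sided permutation p = 0.0185, the smallest possible), while other peaks were 1.67-fold (exact permutation p = 0.0741).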
